A study of Mus musculus with 4 samples.

How the data were processed

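RNA from 4 pooled samples of 3D-retinas, 1 per group, was labelled with Cy3 (50 ng each, per the labels) and hybridised to a 1-colour mouse gene expression array. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the deposited intensity of each spot was background-subtracted and corrected for spatial and multiplicative trends, with surrogate values near background and no normalization between arrays, and the design was annotated on the mm9 build. All 4 arrays lay on a single slide with a single scan, so that slide and scan did not separate the groups, whereas position on the slide and group cannot be told apart.

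The scanner file of the lutein array had been saved at 3 significant digits, and 57 of its gene names had been altered. Gene names were therefore taken from another array of the same design, and probe names were the same on all 4 arrays. The authors' deposited value table holds the linear signal intensity divided by 1 number per array, close to its 75th percentile over all spots; this came from comparing it with the scanner values, where the divisors were 494.2, 434.1, 468.9 and 479.2 for vehicle, 4-OHT, vitamin E and lutein. It is neither logged nor centred per gene, and its column medians were 0.0794, 0.0949, 0.0736 and 0.0847. It served as an alternative.

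Each array held 62976 spots, 59305 of them for genes. No spot was saturated. Between 30411 and 32318 gene spots were well above background. Control spots and spots marked as non-uniform or population outliers were left out (137 to 164 per array). Intensities were log2-transformed, the 75th percentile of each array's gene spots was subtracted, and spots of a probe were averaged. Of 55681 probes 28331 (50.9%) had an accession in the RefSeq table used for current symbols (assembly GRCm38.p6, names only), which replaced 1403 names; all others kept the file's name. The probe with the highest mean over the 4 arrays stood for a gene. Where a gene had 2 or more probes detected on both arrays, 5205 genes for 4-OHT against vehicle, 6 genes had probes at least 2-fold in opposite directions, and of 653 with at least 1 such probe past 2-fold 181 had every detected probe past 2-fold in the same direction. Exon and UTR annotation of mm9 was not used here.

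A gene entered a comparison if it was well above background on at least 1 of the arrays. A dim value was set to the lowest signal well above background on its array, or its own if higher, so that the difference is a bound, written as at least N-fold. Limits of 2-fold, and of 1.5-fold and 4-fold as alternatives, were fixed sizes with no test. Precision is limited by the number of arrays, 1 per group. For 399 probes with 10 spots the within-array SD of log2 signal was 0.10 on each array, over the probes detected there, and at most 0.056% of spot pairs differed by 2-fold.

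The groups, 6 comparisons, 48 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and stood apart at or below percentile 2.5 or at or above 97.5; lists with under 5 measured genes had no percentile. Of 873 listed symbols 870 were on the array. An older synonym in the list for vitamin E and carotenoid handling matched Cenpx, a gene not known for that role. The bipolar list holds Rhox8, paired there with an older gene name in error, and 2 members, Cabp5 and Trpm1, whose probes had opposite signs for 4-OHT against vehicle. Genes were named, per comparison, as the 10 highest and 10 lowest with a gene symbol and detected on both arrays, 3 bounds in each direction, up to 4 members of each list that stood apart or had 3 members past 2-fold, up to 3 of others, and a fixed set of retinal and drug-response genes. The text gives a selection of these, and some genes are not reported here. Return toward vehicle was measured on genes chosen on arrays other than those measured.

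Alternatives were scaling on the median of probes detected on all arrays, quantile normalization, scaling on 7 spike-in probes detected on all arrays of 10, normexp background correction with offset 50 from limma 3.58.1 under R 4.3.3, the mean of a gene's probes, detection on both arrays, no filter, and the authors' value table. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

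The steps were tested on simulated data with spot noise only. For 4-OHT against vehicle, with 20737 genes, 48 of 50 genes given a 3-fold difference were counted and 48 of 50 given 4-fold, against 2 of 50 given 1.5-fold; 0 of 20537 unchanged genes were counted. Of 200 unchanged lists of 20 genes 1.5% stood apart, and all 200 did when shifted by 0.25.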

Results

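Retinas grown in suspension from mouse induced pluripotent stem cells (3D-retinas), whose rods carry a green fluorescent reporter driven by the rod gene Nrl, were profiled on 1-colour gene expression arrays. They were treated on differentiation day 23 and collected on day 25, when the labels place the start of photoreceptor degeneration. The 4 groups were ethanol vehicle, 4-hydroxytamoxifen (4-OHT, an active metabolite of the estrogen receptor modulator tamoxifen, at 5 µM), the same dose of 4-OHT plus the lipid-soluble antioxidant vitamin E (400 µM), and the same dose of 4-OHT plus lutein, a carotenoid of the macula (200 nM). Each group was 1 array of RNA pooled from 24 3D-retinas. No difference below therefore has a replicate check and none has a p-value. Differences are stated as sizes between these arrays, with 2-fold as the fixed limit for counting a gene. Between 51.3% and 54.5% of gene spots were well above background on an array. The spot-to-spot SD of a log2 difference between arrays was 0.14 to 0.15, which covers spot noise and not the variation between cultures.

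The comparison of 4-OHT with vehicle asked which genes differed after exposure to the drug. Rod photoreceptor genes were lower on the 4-OHT array. Of the 21 measured rod genes 14 were at least 2-fold lower, 0 were 2-fold higher, and all 21 lay below 0, with a median log2 difference of -1.48, at percentile 0.0 of 10000 random lists of matched signal. Gnat1, the rod transducin alpha subunit, was 40.8-fold lower (log2 difference -5.35), Slc24a1, the rod sodium-calcium-potassium exchanger, 11.1-fold lower, and Esrrb, an orphan nuclear receptor of rods, 9.19-fold lower. The rod transcription factors Nrl and Nr2e3 differed less, with log2 differences of -0.75 and -0.80, as did the photoreceptor factor Crx at -0.85, all short of 2-fold. This does not extend to transcription factors in general, because the nuclear receptor Esrrb was among the genes with the largest differences. The Gnat1 probe lies on chromosome 9 at 107577023 to 107577082 of the mm9 build.

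Genes shared by rods and cones had the same direction. Of 25 measured genes of the photoreceptor outer segment and synapse 7 were at least 2-fold lower and 1 higher, with a median log2 difference of -0.86 (percentile 0.0). Recoverin (Rcvrn), a calcium sensor of photoreceptors, was 4.32-fold lower and Fscn2, an actin-bundling protein of the outer segment, 3.65-fold lower. Cone genes were mixed. Of 15 measured, 4 were at least 2-fold higher and 2 lower, and the median log2 difference was 0.58 (percentile 99.99). Kcne2, a potassium channel subunit, was 12.9-fold higher, whereas the cone transducin Gnat2 was 2.46-fold lower. The short-wave cone opsin Opn1sw, not well above background in vehicle, was at least 2.93-fold higher. Cone arrestin (Arr3) was 3.97-fold higher by its brightest probe and 0.53 on the log2 scale by another. The green cone opsin Opn1mw and the estrogen receptor Esr1 were not well above background on any array.

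Stress genes were higher on the 4-OHT array. Of 26 measured genes of the integrated stress response and amino acid supply 22 were at least 2-fold higher and 0 lower, with a median log2 difference of 2.27, above all 10000 random lists. The transcription factor Atf3 was 20.8-fold higher, the stress protein Nupr1 19.9-fold, the secreted factor Gdf15 15.5-fold, the amino acid transporter Slc7a3 11.7-fold and the transcription factor Ddit3 2.91-fold. Of 21 immediate early genes 18 were at least 2-fold higher (median 2.17, also above all random lists). Npas4, a neuronal activity-dependent transcription factor, was 63.4-fold higher, the highest of the named genes detected on both arrays, and Fos was 32.6-fold and Egr1 22.5-fold higher. Of 17 inflammation and gliosis genes 13 were at least 2-fold higher (median 2.03, above all random lists), and 8 of the 17 were well above background on 1 of the arrays only. The chemokines Cxcl10 and Ccl2 and the NF-kappaB cofactor Bcl3 were not well above background in vehicle and were at least 23.1-fold, 17.0-fold and 36.9-fold higher. The metal-binding proteins Mt1 and Mt2 were 22.1-fold and 29.8-fold higher, as 2 of the 3 genes past 2-fold in a list of 9. Interferon response genes had a median of 0.83 (percentile 99.61, 4 of 9 past 2-fold). In the oxidative stress list 4 of 27 were past 2-fold, among them Hmox1, the inducible heme oxygenase, with a log2 difference of 3.47, while the list's median was -0.17 (percentile 27.52).

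All 22 measured genes of mitochondrial oxidative phosphorylation lay below 0, with a median of -0.78 (percentile 0.0) and 2 past 2-fold, among them Ndufa4 at 2.49-fold lower. Genes of cholesterol synthesis and uptake had a median of 0.38 (above all random lists), with the sterol sensor Insig1 2.25-fold higher and 25 of 27 short of 2-fold. The extracellular matrix list had a median of 0.68 (percentile 99.9), with Timp1, a metalloproteinase inhibitor, at least 13.6-fold higher. The pigment epithelium list had a median of 0.37 (percentile 98.28), with the melanin enzyme Dct 5.37-fold higher, and the hypoxia and glycolysis list 0.42 (above all random lists), with Vegfa 4.71-fold higher. In the apoptosis list 4 of 20 were at least 2-fold higher, including the BH3-only genes Bbc3 (4.92-fold) and Hrk (4.04-fold). Markers chosen for Muller glia, amacrine, bipolar, horizontal and ganglion cells had medians between -0.35 and -0.07, none of which stood apart from random lists. Of the 46 lists given a percentile, 14 lay above and 4 below the central range, where 2.3 would if list members varied independently. Members of a list may vary together, and random lists also draw transcripts without a gene symbol. The 2.3 is therefore not a chance rate for these lists. Against vehicle, 18 of 47 lists lay above and 4 below with vitamin E, and 17 and 3 of 45 with lutein. Fewer genes were counted there, so lists standing apart did not track the number of counted genes.

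Counts of genes here and below include lincRNAs and transcripts with clone or predicted names. Of 13903 genes with a gene symbol, 816 were at least 2-fold higher with 4-OHT and 473 lower. The median log2 difference of these 13903 was -0.126, against 0.075 for lincRNAs, so 0 is not their neutral level. Of all 22077 genes measured on either array, 1712 were at least 2-fold higher and 695 lower, so that 71.1% of the counted genes were higher. On external spike-in RNA the counts were 1347 and 1190 and the split 53.1%, because that scaling moved the median of all genes by -0.16; the rod median was then -1.63, so the list differences above are best read against all genes.

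**Figure D1:**
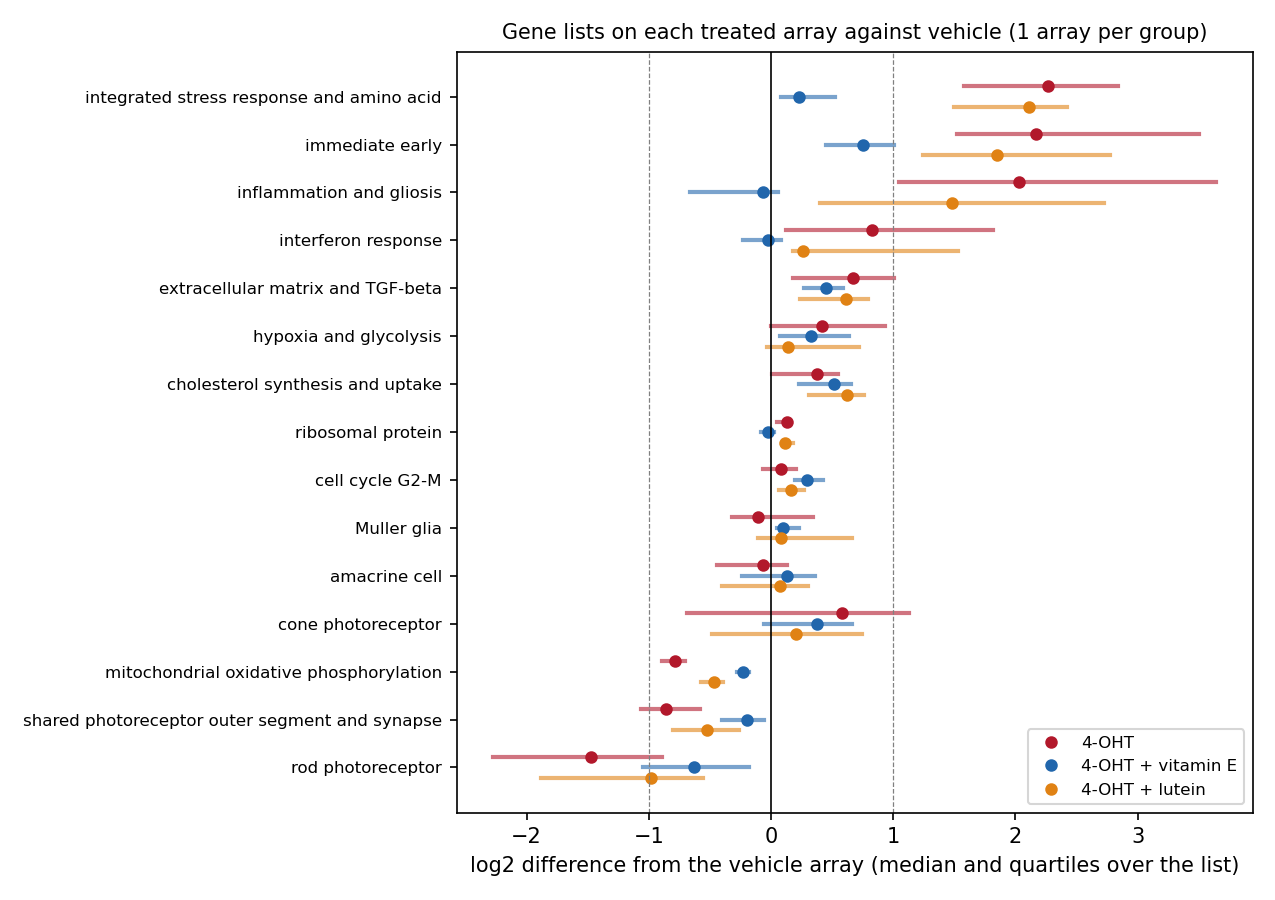
Median log2 difference from the vehicle array (points) with quartiles over the list members (bars) for 15 gene lists on the 4-OHT, 4-OHT + vitamin E and 4-OHT + lutein arrays, with dashed lines at 2-fold. The stress response list lay at 2.27 with 4-OHT and 2.11 with lutein but 0.23 with vitamin E, and the rod list at -1.48, -0.98 and -0.63.

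The comparison of 4-OHT with and without vitamin E asked how the supplement altered the response to the drug. The stress genes were lower with vitamin E. Of 26 stress response genes 22 were at least 2-fold lower than on the 4-OHT array and 0 higher, with a median log2 difference of -1.98 (percentile 0.0). Atf3 was 11.8-fold, Gdf15 11.3-fold, Nupr1 7.91-fold and Ddit3 2.89-fold lower. Immediate early genes had a median of -1.32, with 16 of 21 at least 2-fold lower, Npas4 by 6.84-fold. Inflammation genes had a median of -1.97, with 12 of 17 past 2-fold, among them the cytokine signalling inhibitor Socs3 at 22.0-fold lower and Bcl3, which was not well above background with vitamin E, at least 44.2-fold lower. Mt1 was 12.7-fold and Mt2 20.7-fold lower. Hmox1 was 6.59-fold lower, and the vitamin C transporter-family gene Slc23a3 33.4-fold lower. Among p53 targets 5 of 16 were at least 2-fold lower, Cdkn1a by 4.19-fold, but 7 of 16 lay above 0 and the median of -0.18 turned to 0.04 on spike-in scaling.

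Rod genes were higher with vitamin E than with 4-OHT alone. Of 21, 9 were at least 2-fold higher and 0 lower, with a median of 0.90 (above all random lists). Gnat1 was 5.29-fold, Esrrb 3.55-fold and the rod channel subunit Cnga1 2.78-fold higher, while Nrl and Nr2e3 had log2 differences of 0.59 and 0.83. The shared photoreceptor list had a median of 0.65 (above all random lists), with 5 of 25 at least 2-fold higher and Rcvrn at 2.43-fold. All 22 oxidative phosphorylation genes lay above 0, with a median of 0.56 (above all random lists) and 0 past 2-fold. The sterol efflux list had a median of 0.56 (percentile 99.93), and the cholesterol synthesis list 0.07 (percentile 11.59). The genes Map3k19, Ifnk and Baiap3, the largest of those well above background on the vitamin E array only, were at least 7.27-fold, 6.73-fold and 6.19-fold higher, each on a single spot.

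Of 13942 genes with a gene symbol, 203 were at least 2-fold higher with vitamin E than with 4-OHT alone and 712 lower. The median log2 difference of these 13942 was 0.166, against -0.138 for lincRNAs, so 0 is not their neutral level. Among all 22148 genes 329 were at least 2-fold higher and 1952 lower, so that 14.4% of the counted genes were higher. The counts were 735 and 1486 on spike-in scaling (33.1% higher), which moved the median of all genes by 0.21, and 665 and 1552 after quantile normalization (30.0% higher). Of 47 lists, 6 lay above and 9 below the central range of random lists.

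The comparison of 4-OHT with and without lutein put the same question to the carotenoid. The stress response list stayed near its 4-OHT level. Its median difference was -0.19 (percentile 0.0), with 23 of 26 genes below 0 and 0 of 26 past 2-fold in either direction. Atf3 had a log2 difference of -0.48, Ddit3 -0.12 and Hmox1 -0.33. Immediate early genes had a median of -0.33 with 2 of 21 at least 2-fold lower, including Npas4 at 2.03-fold, and inflammation genes a median of -0.57 with 2 of 17 past 2-fold, including Bcl3 at 2.15-fold lower.

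Rod genes had a median of 0.39 with lutein (above all random lists), and 18 of 21 lay above 0, but 1 was past 2-fold, Gnat1, at 2.19-fold higher. Rcvrn had a log2 difference of 0.68. Oxidative phosphorylation genes had a median of 0.31 with all 22 above 0 (above all random lists), and cholesterol synthesis genes 0.25 with 26 of 27 above 0 (percentile 99.61). All genes with a gene symbol had a median of 0.126 in this comparison, against -0.051 for lincRNAs. For such genes 0 is therefore not the neutral level. Kcne2 was 3.69-fold lower, and the non-coding RNAs Kcnq1ot1 and Vax2os were 3.52-fold and 4.65-fold lower. The gene with the largest bound, H2-M9, was at least 12.6-fold lower and rests on 1 spot. Esr2, the second estrogen receptor gene, was 2.28-fold lower with lutein and 3.13-fold lower with vitamin E than with 4-OHT alone. It was 2.48-fold higher with 4-OHT than in vehicle, and against vehicle its log2 differences were 0.12 with lutein and -0.34 with vitamin E. In all, 253 of 21989 genes were at least 2-fold higher with lutein than with 4-OHT alone and 845 lower. The counts were 75 and 616 when a gene had to be well above background on both arrays. Among 13844 genes with a gene symbol, 104 were at least 2-fold higher and 200 lower.

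**Figure D2:**
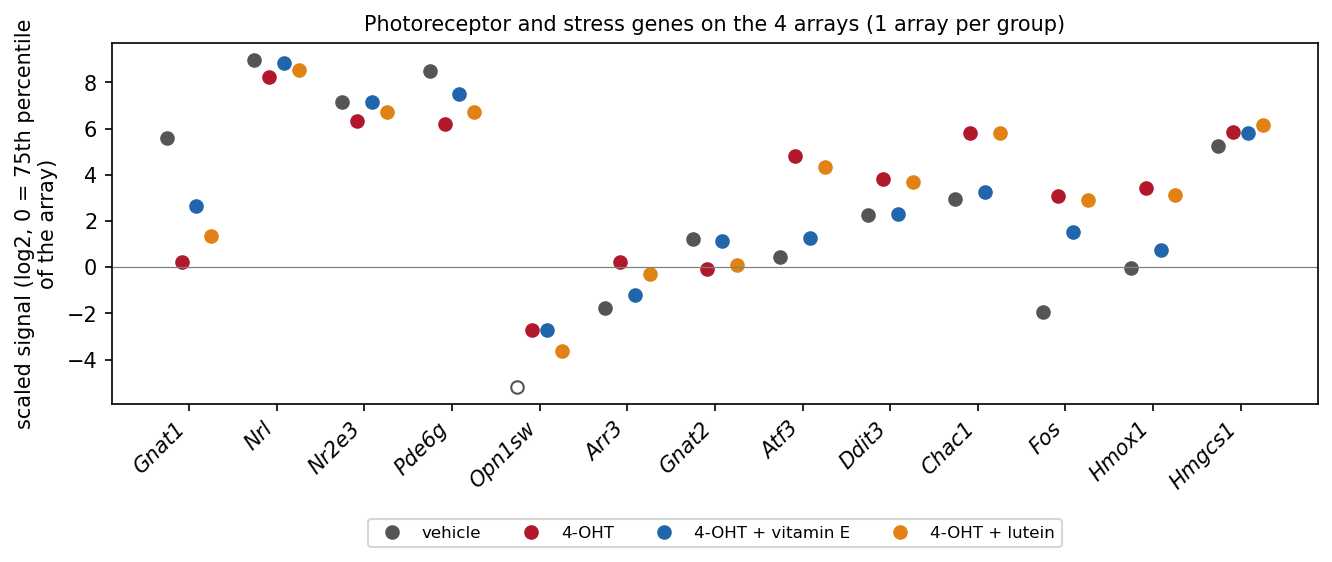
Scaled signal of 13 photoreceptor and stress genes on the 4 arrays (log2, with 0 at the 75th percentile of each array); open points mark signals not well above background. Atf3 lay 4.38 above vehicle with 4-OHT, 3.89 with lutein and 0.81 with vitamin E, and Gnat1 lay below vehicle on all 3 arrays with 4-OHT.

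Against vehicle, the vitamin E sample differed in fewer genes than the lutein sample, with 232 higher and 424 lower of 21361, against 733 higher and 319 lower of 21351. Among genes with a gene symbol, 152 were higher and 147 lower of 13718 with vitamin E, and 462 and 205 of 13692 with lutein. Stress response genes had a median of 0.23 with vitamin E, 2 of 24 past 2-fold, and of 2.11 with lutein, 22 of 25 past 2-fold. Immediate early genes were above vehicle with both, with medians of 0.76 and 1.85, and with vitamin E Fos and Egr1 still had log2 differences of 3.47 and 3.33. Rod genes were below vehicle with both, with medians of -0.63 (6 of 21 at least 2-fold lower) and -0.98 (10 of 21), and Gnat1 had log2 differences of -2.95 and -4.22. Cholesterol synthesis genes were above vehicle with both, at 0.52 and 0.62 (above all random lists in each case). For vitamin E the split was 35.4% higher, against 45.5% after quantile normalization and 46.7% with normexp background.

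The supplements were also set against each other directly, although their doses differed. With vitamin E 106 of 21433 genes were at least 2-fold higher than with lutein and 784 lower. Among 13753 genes with a gene symbol, 47 were higher and 370 lower. Of 25 stress response genes 21 were at least 2-fold lower (median -1.60, percentile 0.0). Atf3 had a log2 difference of -3.08. Rod genes had a median of 0.48 (above all random lists) with 2 of 21 past 2-fold.

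Return toward vehicle was measured as a shift in the vehicle direction, which includes shifts past the vehicle level, on genes chosen without the arrays used to measure it. On 862 genes at least 2-fold from vehicle with lutein, vitamin E lay in the vehicle direction from 4-OHT alone by a median log2 of 0.94, and 85.2% of the genes lay on that side. On 480 genes at least 2-fold from vehicle with vitamin E, the corresponding median for lutein was -0.11, with 41.2% on that side, and its sign turned with the choice of genes and background. It also depended on direction, at 0.14 for the 178 genes above vehicle and -0.45 for the 302 below, whereas for vitamin E the medians were 1.27 and 0.54. The gene sets differ, so these values do not rank the supplements. On 2094 genes at least 2-fold from vehicle with 4-OHT, a set chosen after the data were seen and on arrays other than those compared, vitamin E lay in the vehicle direction from lutein by a median of 0.54, on 90.5% of genes.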

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

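An external RNA control probe (ERCC-00113) was well above background on the 4-OHT array and not on vehicle, although no comparison uses such probes. Its median signal over 28 spots was 55.6 with 4-OHT, 16.9 with vehicle, 13.3 with vitamin E and 27.2 with lutein. Of 96 such control probes, 3 others were detected on most spots of every array. The cause was not tested.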

How the results depend on the processing

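Of 832 recomputed list medians 11 were counted as turned in sign. Only lists that stood apart could be so counted, and turns in the other lists covered are not included. Of 2055 values of named genes past 2-fold 1500 moved by less than the spot-to-spot SD, 553 by more, and 2 turned sign. Part of the 1500 was fixed in advance. Detection on both arrays and no filter cannot move a gene detected on both arrays. The mean of probes cannot move a gene with 1 detected probe. Median scaling and the authors' value table moved the median of all genes by only -0.017 to 0.017. The 1500 is therefore not a measure of robustness. Below, counts are higher then lower; except where a value or the setting's construction shows it, the cause was not tested. No paired analysis was possible because each group had 1 array.

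For 4-OHT against vehicle (1712, 695) normexp background gave 903 and 350, no filter 3147 and 1487, 1.5-fold 3348 and 2977, 4-fold 382 and 76, and spike-in scaling 1190 lower. For vitamin E against 4-OHT (329, 1952) normexp gave 133 and 1044, no filter 969 and 3713, 1.5-fold 1895 and 3456, 4-fold 33 and 519, with 665 higher after quantile normalization and 735 on spike-in scaling. For lutein against 4-OHT (253, 845) normexp gave 84 and 307, no filter 1342 and 2135, 1.5-fold 845 and 2012, 4-fold 65 and 50, and detection on both arrays 75 higher.

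For vitamin E against vehicle (232, 424) normexp gave 84 and 96, detection on both arrays 130 and 217, no filter 874 and 1560, 1.5-fold 939 and 1416, and 4-fold 38 and 57. For lutein against vehicle (733, 319) they gave 351 and 138, 473 and 204, 2106 and 1167, 1963 and 1240, and 161 and 47. For vitamin E against lutein (106, 784) they gave 43 and 279, 34 and 450, 664 and 2429, 473 and 1891, and 29 and 154, with 153 and 570 after quantile normalization. Normexp with an offset compresses dim differences by construction.

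Return toward vehicle with vitamin E (0.94) was 1.32 on genes picked on 4-OHT against vehicle, which shares the 4-OHT array and so is inflated by its noise, 0.52 at 1.5-fold, 2.20 at 4-fold and 1.09 with normexp. With lutein (-0.11) it turned to 0.75 on genes picked that way, 0.19 at 4-fold and 0.062 with normexp. The shift of vitamin E from lutein in the vehicle direction (0.54), added after the data were seen, was 0.50 to 0.52 under quantile, spike-in and normexp.

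Medians of lists that stood apart turned sign mainly on spike-in scaling, where the shift of all genes exceeds them. With 4-OHT these were lysosome -0.085, p53 targets -0.065 and ribosomal protein -0.025. With vitamin E against 4-OHT they were metallothionein 0.013, heat shock 0.006, p53 targets 0.037 and ribosomal protein 0.08. With lutein against 4-OHT, heat shock turned to 0.063. Without the filter, xenobiotic genes with 4-OHT turned to -0.027, mesenchyme genes with vitamin E to -0.089 and bipolar genes with lutein to 0.13. By the mean of probes, Trpm1 with 4-OHT turned to -0.19 and Pdzd7 with lutein to 0.58.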

Other observations

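The test of equal rod loss, whose limit replaced an earlier one after its value was known, and that of the sterol list were chosen only after the results were seen. Transcripts without a gene symbol were more often higher on the 4-OHT array than named genes. Of 2842 measured lincRNA transcripts 10.17% were at least 2-fold higher than vehicle and 2.92% lower, and of 5332 other transcripts with clone or predicted names 11.38% were higher, against 5.87% of 13903 named genes. With lutein 3.84% of lincRNAs, 3.38% of the other unnamed transcripts and 3.37% of named genes were higher than vehicle. With vitamin E the shares were 0.91%, 1.12% and 1.11%, so the excess of higher transcripts was seen mainly on the 4-OHT array. The classes also differed without that array. With vitamin E 3.86%, 3.5% and 1.07% were lower than vehicle, and 6.15%, 4.99% and 2.69% were lower than with lutein. Against the 4-OHT array, 14.67% of lincRNAs, 15.35% of the other unnamed transcripts and 5.11% of named genes were lower with vitamin E. With lutein the shares were 8.04%, 7.85% and 1.44%. The imprinted antisense RNA Airn was 12.9-fold lower with vitamin E than with 4-OHT alone by its brightest probe, and the log2 differences of its 4 detected probes ran from -3.70 to -1.12.

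Rod genes were lower with 4-OHT under every scaling tried. Array scaling would have brought the rod median above -1 in at least 1 alternative, and the value nearest to 0 was -1.31. These alternatives moved the median of all genes by only -0.158 to 0.025. The test thus had little room to fail and covers only the scalings tried. An equal loss of all rods would lower rod genes by a like amount, whereas the SD over the list was 1.18, above a limit of 0.69 set from all genes detected on the vehicle and vitamin E arrays. Loss of part of the rods and lower transcription in the remaining rods were not separated, and position on the slide cannot be told apart from group.

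The stress response list was high with 4-OHT and with 4-OHT and lutein, and near vehicle with vitamin E. Scaling would have brought its vitamin E median against 4-OHT above -1, and the nearest value to 0 was -1.76. The alternatives moved the median of all genes by only -0.028 to 0.213, so this test too had little room to fail. That the vitamin E array held a sample without 4-OHT cannot be told apart from an effect of the supplement, because vitamin E alone was not measured and each group was 1 array. The sterol list was above vehicle there, at 0.52, as on the other 4-OHT arrays, and rod and immediate early genes kept differences from vehicle in the 4-OHT direction, which an unexposed sample would need vitamin E or culture variation to give.

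The excess of unnamed transcripts among genes higher with 4-OHT could come from background on dim probes. At matched signal the excess over named genes was 2.85 percentage points, above the 1.63 of the highest of 1000 shuffles, so dimness did not account for all of it, but the excess was larger before matching and part of it went with brightness. Signal from both strands, as genomic DNA in the labelling would give, predicted that at least 50% of lincRNA regions with 1 strand higher would have the other strand at least 1.5-fold higher; 27 of 125 did (21.6%), and 15.8% to 22.2% of all regions do. No biological explanation was tested.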
